A study of Homo sapiens with 4 samples.

How the data were processed

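ETS1 is a transcription factor of the ETS family, whose members bind DNA sites with a GGAA core. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA fragments bound by a protein with an antibody, and stretches with more fragments than the background are listed as peaks. The study mapped ETS1 by ChIP-seq in HEYA8 and OVCAR8, established human ovarian cancer cell lines grown untreated in serum-containing medium. Of the 4 samples described, 2 are ETS1 immunoprecipitations and the others are sheared input DNA of the same lines. There is 1 library of each kind per line and no replicate, so the spread between cultures cannot be estimated. Every p-value below describes these lists, not the cell lines.

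Each immunoprecipitation came with a deposited list of 3 columns (chromosome, start and end) and nothing else. The deposited values are therefore genomic positions in base pairs, with no score, fold, p-value or count of reads. Sequencing depth and peak height are unknown, and no interval for an occupancy level can be given. Reads were aligned with Bowtie2 2.0.6 to the hg19 build, per the submitters' processing notes. The peak caller, its threshold, the treatment of duplicate reads and the way input DNA entered the call are not given in the sources used here. The lists hold intervals of nearly one size, which set how far apart the midpoints of overlapping peaks can be. Peaks were listed per line, not on pooled libraries. Whether starts count from 0 or from 1 is not stated, and positions are printed as listed.

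Groups were taken from the sample titles. A peak was called shared when it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1), and line-only otherwise. The overlap expected by chance came from 1000 circular shifts of the OVCAR8 peaks within the stretch of each chromosome that the lists cover, with a one-sided empirical p. The difference in width between shared and line-only peaks was given as the probability that a shared peak is the wider of a random pair, with 100000 label permutations, two-sided. Peaks per chromosome were compared over 23 chromosomes (1 to 22 and X) with a chi-square statistic and 100000 permutations of the list labels. Single chromosomes and regions were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the chromosomes or over the regions tested. Shares carry 95% Wilson intervals over peaks, and log2 ratios carry 95% Wald intervals. Neighbouring peaks are not independent, so these intervals and the Fisher tests understate the error. Counts were therefore repeated with line-only peaks of 1 line that lay within 5 kb of each other counted once.

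The overlap with circular shifts, the comparison by width, the chi-square test over chromosomes and the alternatives for the overlap that counts as shared were chosen before the data were examined. The alternative with a reciprocal overlap used 200 shifts in place of 1000. Fisher's tests, the shifts by 50 to 500 kb, the distances between midpoints and to the nearest peak of the other line, and the counting of neighbours once were added after the data had been seen. The plan ranked peaks by a score and, without one, by width. Widths are heavily tied, so the place of a peak in the file was added as a ranking after the data had been seen. Comparisons of 5 Mb regions (those with at least 5 line-only peaks; 0.5 added to each count for log2 ratios), of runs and clusters of line-only peaks, and of line-only peaks per chromosome were also added then. The rule for named peaks was fixed beforehand, but it asked for a score. File order stood in for it, giving the first 10 peaks of each list and the first 5 of each list with no peak of the other list within 5 kb. Any other peak, cluster or region, including chromosome 3 beyond 150 Mb and chromosome 6 at 25 to 30 Mb, was named after its values were seen, and regions of 5 and 10 Mb were both viewed before 5 Mb was settled on. Peaks are not replicates, so p-values and intervals over peaks describe these lists.

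The plan also held the share of peaks at promoters, genes with a nearby peak, 17 gene lists and 9 sequence motifs. These need an hg19 sequence or annotation, which was not used here, so no peak was assigned to a gene and the ETS1 and PTK2 genes named in the plan were not analysed. The input libraries were not analysed here. The analysis was tested on simulated lists of 6000 intervals each. With 3000 shared intervals planted, 3006 were found, a 5 Mb region with planted line-only intervals was called, and 0 regions were called in lists without a planted difference. The simulated intervals were placed independently, whereas the line-only peaks of these lists are clustered. The simulation therefore gives no rate of false calls for these lists. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.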

Results

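ETS1 binding was mapped in HEYA8 and OVCAR8 ovarian cancer cells, with 1 immunoprecipitated library per line. The HEYA8 list held 6431 peaks on 24 chromosomes and the OVCAR8 list held 6267 peaks on 23. The difference was a single HEYA8 peak on the Y chromosome, which was left out of comparisons by chromosome. Peaks were short and uniform, with a median width of 498 bp in both lists and a minimum of 298 bp in HEYA8 and 300 bp in OVCAR8. Together the peaks covered 3.19 Mb of the genome in HEYA8 and 3.11 Mb in OVCAR8. No peaks overlapped within a list, and the median gap between neighbours was 96.1 kb in HEYA8 and 105 kb in OVCAR8. Read depth was not part of the lists.

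ETS1 peaks were unevenly spread over the chromosomes, and in much the same way in both lines. Chromosome 19, known for its high gene density, carried 9.0 peaks per Mb of its covered stretch in HEYA8 and 9.41 in OVCAR8. Chromosome 17 followed with 4.80 and 4.91 peaks per Mb. The median over 23 chromosomes was 2.00 peaks per Mb in HEYA8 and 1.98 in OVCAR8. The X chromosome had 0.681 and 0.635 peaks per Mb, and chromosome 4 had 0.970 and 0.954. Chromosome 1 held the most peaks, 708 in HEYA8 and 648 in OVCAR8.

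The first comparison asked how far the ETS1 sites of the lines coincide. A total of 3481 peaks were shared, each overlapping exactly 1 peak of the other list. They made up 54.1% of the HEYA8 list (95% interval 52.9 to 55.3) and 55.5% of the OVCAR8 list (54.3 to 56.8). This left 2950 peaks listed only in HEYA8 and 2786 listed only in OVCAR8. Random placement of the OVCAR8 peaks on the same chromosomes gave 18.3 ± 4.50 shared peaks (SD over 1000 placements, at most 35), so the observed number was 190-fold higher (one-sided circular permutation p = 0.001, the smallest that 1000 placements can give). Shifting the OVCAR8 peaks by only 50 to 500 kb, which keeps them in the same part of the chromosome, gave 38.9 ± 6.30, and the excess was then 89.6-fold (permutation p = 0.001, again the smallest possible). Neither placement kept peaks at promoters, so how far the excess reflects ETS1 in particular was not tested.

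Shared peaks were also centred close together. Their midpoints lay a median of 124 bp apart (quartiles 57 and 223.5 bp), against 246 bp by chance (the median offset of overlapping peaks in each random placement, averaged over the placements). Of the shared pairs, 41.7% had midpoints within 100 bp and 7 had identical midpoints. A pair on chromosome 11, 62608868 to 62609369 (hg19), had the same boundaries in both lists and stood at place 2 in the HEYA8 file and place 1 in the OVCAR8 file.

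Line-only peaks were often close to a peak of the other line. Of the HEYA8-only peaks, 960 (32.5%) had an OVCAR8 midpoint between 500 bp and 5 kb away, against 4.47 ± 0.424% (SD over 200 shifts) when the OVCAR8 list was moved by 50 to 500 kb. For OVCAR8-only peaks the number was 851 (30.5%), against 4.67 ± 0.449%. The observed values lay above the highest of the 200 shifts, 5.76% and 5.78%. Peaks with no peak of the other line within 5 kb numbered 1980 in HEYA8, 30.8% of its list (29.7 to 31.9), and 1925 in OVCAR8, 30.7% (29.6 to 31.9).

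The next comparison asked which peaks were shared. Wider peaks overlapped the other list more often than narrow ones. With each list divided by width into 4 equal classes, 39.2% of the narrowest HEYA8 class were shared (36.8 to 41.6) and 63.3% of the widest (60.9 to 65.6). In OVCAR8 the shares were 43.9% (41.5 to 46.4) and 62.9% (60.5 to 65.3). A shared peak was the wider of a random pair of a shared and a line-only peak with a probability of 0.610 in HEYA8 and 0.588 in OVCAR8 (permutation p = 1e-05 for each, the smallest that the permutations can give). Most widths differed by only a few base pairs: the wider 3 of the 4 classes in HEYA8 began at 494 bp and in OVCAR8 at 495 bp.

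The files were not in genome order, and a peak's place in the file separated shared from line-only peaks more clearly than its width. With each file divided into 10 equal parts, 88.0% of peaks in the first part of the OVCAR8 file were shared (85.3 to 90.3) and 16.1% in the last (13.5 to 19.2). In HEYA8 the share was 80.1% (76.9 to 83.0) in the first part, 82.6% (79.5 to 85.3) in the next and 16.5% (13.8 to 19.6) in the last. The probability that a shared peak stood earlier than a line-only peak was 0.755 in HEYA8 and 0.781 in OVCAR8 (permutation p = 1e-05 each). Across the 3481 shared peaks, places in both files were correlated with a Spearman rho of 0.65 (permutation p = 1e-05, across peaks, which are not independent replicates). Place and width were not separate rankings: earlier peaks tended to be wider (Spearman rho of place and width -0.29 in HEYA8 and -0.27 in OVCAR8). The files do not state what the order means.

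**Figure D1:**
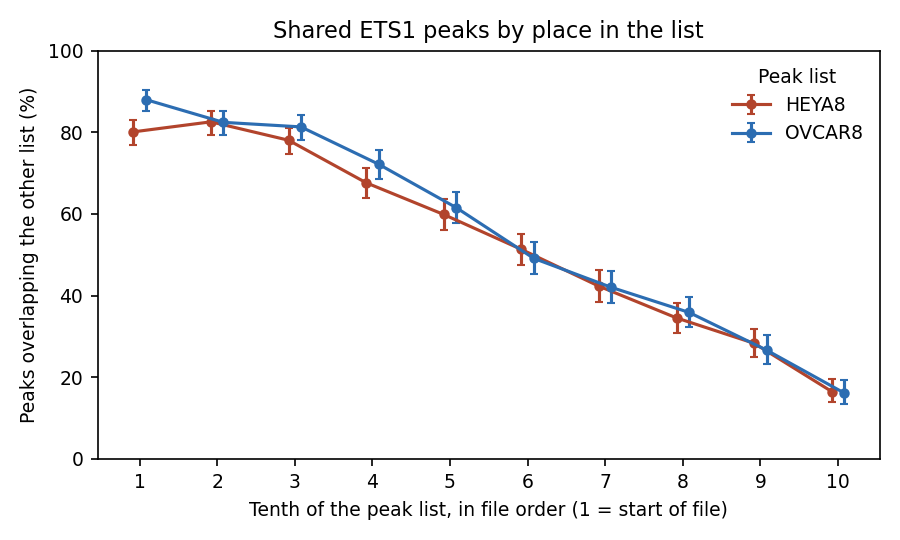
Percentage of ETS1 peaks that overlapped a peak of the other list (vertical axis), for 10 successive equal parts of the HEYA8 and OVCAR8 files (horizontal axis). Points are shares and bars are 95% Wilson intervals over peaks; the share fell from 80.1% to 16.5% in HEYA8 and from 88.0% to 16.1% in OVCAR8.

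Of the first 10 peaks in the HEYA8 file, 8 were shared, and all of the first 10 in the OVCAR8 file were. The exceptions in HEYA8 were at place 1, on chromosome 12 from 6646802 to 6647303, and at place 3, on chromosome 10 from 17271439 to 17271940. Their midpoints lay 2.81 kb and 0.705 kb from the nearest OVCAR8 peak. Other sites near the start of both files were on chromosome 1 from 86046625 to 86047126 in HEYA8 (place 4 there, place 2 in OVCAR8), on chromosome 12 from 6961373 to 6961874 (places 5 and 3), on chromosome 6 from 74230546 to 74231047 (places 6 and 10) and on chromosome 8 from 67579309 to 67579810 (places 8 and 7). A peak on chromosome 7 from 5567798 to 5568298 was at place 7 in HEYA8, and its partner stood at place 144 in OVCAR8. The remaining shared peaks among the first 10 of HEYA8 began at 41438437 on chromosome 17 and at 45187246 on chromosome 1. Those among the first 10 of OVCAR8 not yet named began at 120729416 on chromosome 12, at 82997039 on chromosome 11, and at 16840327, 28974937 and 147993990 on chromosome 1.

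Peaks with no peak of the other line within 5 kb also occurred early in the files. In HEYA8 the first of these was on chromosome 1 from 209849035 to 209849536, at place 14, and the nearest OVCAR8 peak was 698 kb away. The others were on chromosome 17 from 41400558 to 41401059 (place 33, 7.52 kb away), chromosome 2 from 38709057 to 38709558 (place 72, nearest OVCAR8 peak 184 kb away), chromosome 4 from 74735412 to 74735912 (place 81, 240 kb away) and chromosome 1 from 8921072 to 8921565 (place 103, 6.4 kb away). In OVCAR8 such sites began later in the file. They were on chromosome 19 from 36914451 to 36914947 (place 99, nearest HEYA8 peak 66.2 kb away), chromosome 17 from 56756588 to 56757086 (place 135, 13.3 kb away), chromosome 4 from 1319478 to 1319978 (place 169, 36.6 kb away), chromosome 2 from 106015815 to 106016315 (place 182, 62.3 kb away) and chromosome 6 from 34203885 to 34204386 (place 224, 9.46 kb away).

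The last set of comparisons asked where in the genome the lines differed. Chromosomes 3 and 9 held different shares of the lists. Chromosome 3 carried 443 HEYA8 peaks and 338 OVCAR8 peaks, a log2 ratio of list shares of 0.35 (Fisher's exact test, adjusted p = 0.00782). Chromosome 9 carried 262 and 336, a log2 ratio of -0.40 (Fisher's exact test, adjusted p = 0.00782). Chromosome 12 had 414 HEYA8 and 337 OVCAR8 peaks and chromosome 6 had 341 and 400, and both missed the threshold (Fisher's exact test, adjusted p = 0.0672 each). Over all 23 chromosomes the lists differed by a chi-square statistic of 51.8 (permutation p = 0.00037).

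Line-only peaks gave the same differences in count, because shared peaks pair 1 to 1 and add equally to both lists. They are therefore not a second result. The tests over all peaks counted each shared site in both lists as if independent, and among line-only peaks 2 more chromosomes passed the threshold. Line-only peaks of HEYA8 outnumbered those of OVCAR8 on chromosome 3 (234 and 129, log2 ratio of shares 0.78, 95% interval 0.48 to 1.08, Fisher's exact test, adjusted p = 6.11e-06) and on chromosome 12 (203 and 126, 0.61, 0.29 to 0.92, adjusted p = 0.000775). OVCAR8 had more on chromosome 9 (102 and 176, -0.87, -1.21 to -0.53, Fisher's exact test, adjusted p = 6.11e-06) and on chromosome 6 (133 and 192, -0.61, -0.92 to -0.30, adjusted p = 0.000759). Counting line-only peaks of 1 line within 5 kb once left all 4 chromosomes past the threshold, with adjusted p of Fisher's exact test from 2.51e-05 on chromosome 9 to 0.00377 on chromosome 6. The other 19 chromosomes did not pass the test for line-only peaks.

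**Figure D2:**
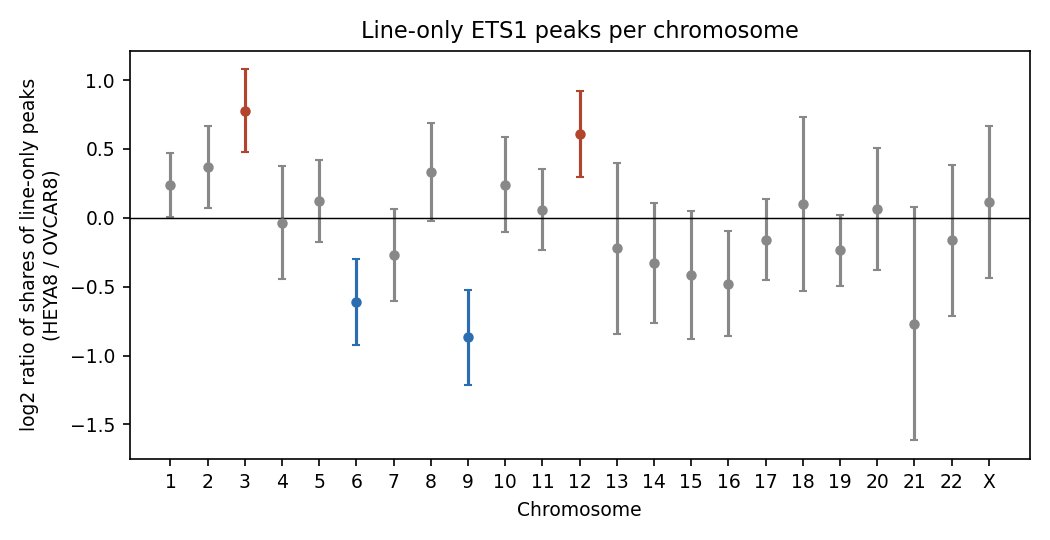
Log2 ratio of the HEYA8 share to the OVCAR8 share of line-only ETS1 peaks (vertical axis) on each chromosome (horizontal axis). Points are ratios and bars are 95% Wald intervals over peaks; chromosomes past the adjusted threshold of 0.05 are red where HEYA8 was higher (3 and 12) and blue where OVCAR8 was higher (6 and 9), and the rest are grey.

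The differences were laid out differently along these chromosomes. On chromosome 9 OVCAR8 had more line-only peaks in 12 of 14 stretches of 10 Mb and HEYA8 in 1. On chromosome 12 HEYA8 had more in 10 of 14 and OVCAR8 in 1. On chromosome 3 HEYA8 had more in 14 of 20 stretches and OVCAR8 in 5, and the balance changed along the chromosome. Up to 100 Mb there were 72 HEYA8-only and 83 OVCAR8-only peaks, from 100 to 150 Mb 57 and 29, and beyond 150 Mb 105 and 17. These boundaries were chosen after the counts were seen. With peaks within 5 kb counted once, the numbers beyond 150 Mb were 86 and 16. On chromosome 6 HEYA8 had more line-only peaks in 9 stretches and OVCAR8 in 8 of 18.

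The net difference on chromosome 6 came largely from a single region, chosen after the counts were seen. Between 25 and 30 Mb, the HEYA8 list had 64 peaks and the OVCAR8 list had 113. Of the HEYA8 peaks there, 60 were shared, or 93.8% (85.0 to 97.5), while 53 of the OVCAR8 peaks were OVCAR8-only and 4 of the HEYA8 peaks were HEYA8-only (Fisher's exact test over 376 regions, adjusted p = 2.3e-10). On the rest of chromosome 6 the log2 ratio of line-only shares was -0.19 (-0.53 to 0.15), which averages stretches of opposite direction. Every 10 Mb stretch from 50 to 100 Mb had more OVCAR8-only peaks, up to 13 against 3 HEYA8-only peaks at 70 to 80 Mb. Beyond 100 Mb every stretch had more HEYA8-only peaks or equal numbers. None of these stretches passed the adjusted threshold. The region at 25 to 30 Mb was also crowded with peaks from the start of both files. It held 22 of the 643 earliest HEYA8 peaks and 47 of the 626 earliest OVCAR8 peaks. That was 34.4% of the region's HEYA8 peaks, against 9.75% of HEYA8 peaks elsewhere, and 41.6% of its OVCAR8 peaks, against 9.41% elsewhere (Fisher's exact test, unadjusted p = 9.77e-08 and 5.41e-19).

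Altogether 12 of 376 regions of 5 Mb passed the adjusted threshold, 3 with more HEYA8-only and 9 with more OVCAR8-only peaks, and 56 had an unadjusted p under 0.05. With 10 Mb regions the balance was the other way, 9 with more HEYA8-only and 7 with more OVCAR8-only peaks, so the split between the lines depended on region size. The 9 included every 10 Mb region of chromosome 3 from 150 to 200 Mb, a single stretch that was counted once per region. HEYA8-only peaks prevailed on chromosome 1 at 205 to 210 Mb (19 and 3), on chromosome 11 at 10 to 15 Mb (21 and 4) and on chromosome 2 at 205 to 210 Mb (11 and 0). OVCAR8-only peaks prevailed, besides chromosome 6, on chromosome 19 at 5 to 10 Mb (5 HEYA8-only and 24 OVCAR8-only) and at 20 to 25 Mb (3 and 19). They also prevailed on chromosome 16 at 0 to 5 Mb (19 and 44), on chromosome 1 at 225 to 230 Mb (2 and 16), on chromosome 9 at 115 to 120 Mb (0 and 11) and 120 to 125 Mb (0 and 10), on chromosome 7 at 145 to 150 Mb (0 and 11) and on chromosome 15 at 35 to 40 Mb (0 and 9). When peaks of 1 line within 5 kb were counted once, only 1 region passed, chromosome 6 at 25 to 30 Mb (4 and 45, Fisher's exact test, adjusted p = 2.57e-07). All 12 then kept their direction. These regions had been picked for uneven counts, and counting neighbours once trims counts, so a reversal was unlikely from the outset. Neither the kept directions nor the unadjusted p-values are separate evidence of unevenness. The log2 ratio went from -4.61 to -4.39 on chromosome 7, from -4.61 to -4.52 on chromosome 9 at 115 to 120 Mb, from -1.27 to -1.28 on chromosome 16 and from 4.44 to 4.25 on chromosome 2. It moved further on chromosome 15 (-4.33 to -3.17), on chromosome 19 at 5 to 10 Mb (-2.24 to -1.82) and on chromosome 11 (2.17 to 1.79). In 3 regions (both on chromosome 9, and chromosome 1 at 225 to 230 Mb) the counts did not change at all, yet adjusted p rose to 0.0884 in Fisher's exact test. Counting once had lowered the list totals unequally, to 2625 HEYA8-only and 2633 OVCAR8-only sites. With the same counts, this alone raised the unadjusted p of these regions, for example from 0.000352 to 0.000967 on chromosome 9 at 115 to 120 Mb (Fisher's exact test). An unadjusted p under 0.05 was kept by 11 regions; the exception, on chromosome 15, had 4 OVCAR8-only sites left and was not adjusted. With boundaries moved midway 4 regions passed, on chromosome 6 at 27.5 to 32.5 Mb (15 and 59), chromosome 7 at 147.5 to 152.5 Mb (0 and 19), chromosome 1 at 207.5 to 212.5 Mb (20 and 1) and chromosome 2 at 112.5 to 117.5 Mb (19 and 2).

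**Figure D3:**
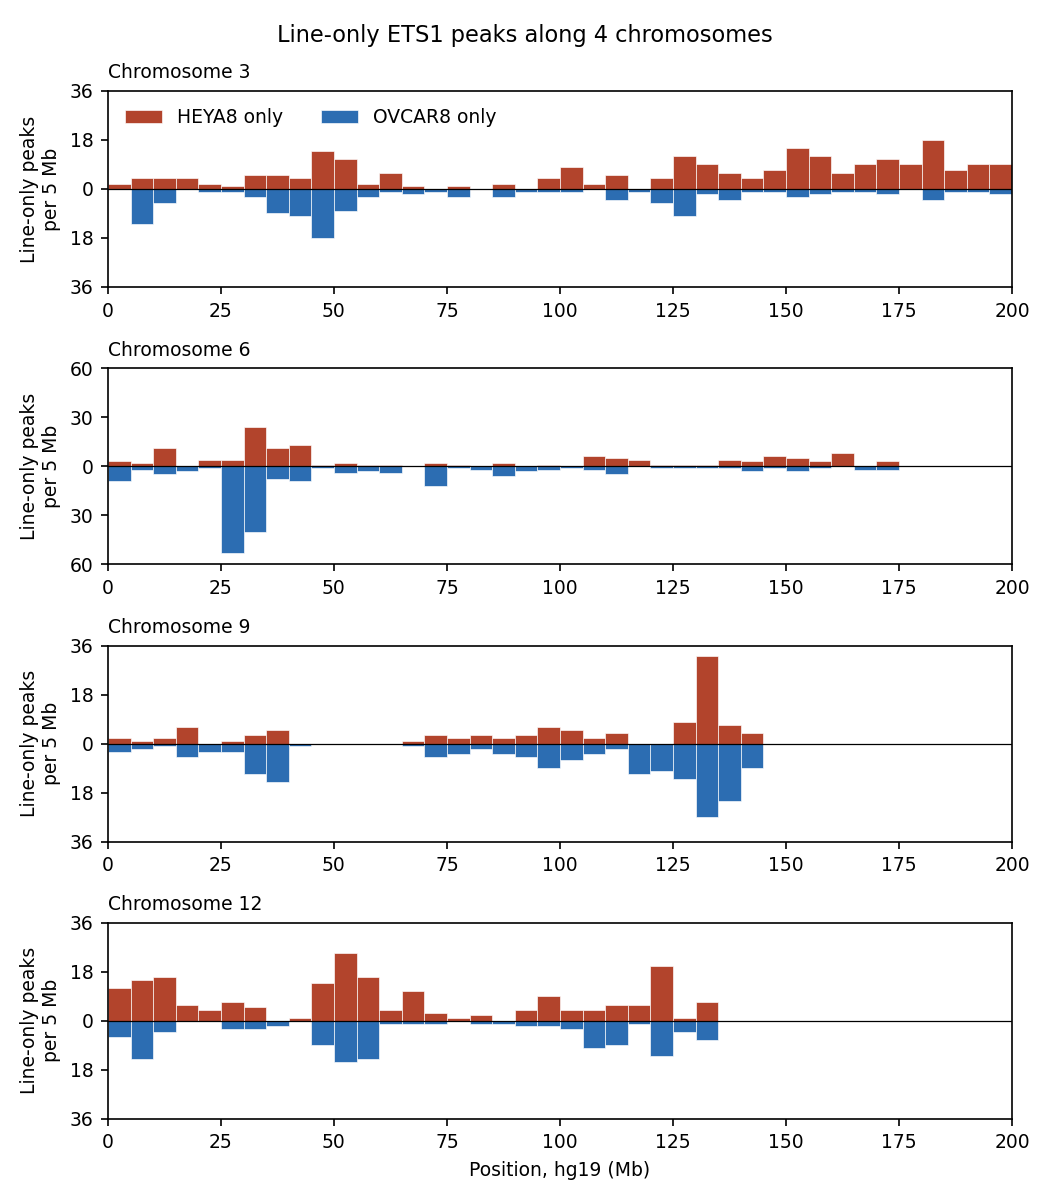
Number of HEYA8-only (upward, red) and OVCAR8-only (downward, blue) ETS1 peaks per 5 Mb (vertical axis) along chromosomes 3, 6, 9 and 12 (horizontal axis, hg19 position in Mb). The vertical scale of chromosome 6 is wider than that of the others; its 25 to 30 Mb region held 4 HEYA8-only and 53 OVCAR8-only peaks, and chromosome 3 beyond 150 Mb held 105 and 17.

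Some stretches held an unbroken run of line-only peaks of 1 line, with neither a shared peak nor a peak of the other line between them. The longest comprised 20 HEYA8-only peaks on chromosome 1 from 206785344 to 210001489, a stretch of 3.22 Mb. When the line labels of line-only peaks were permuted 1000 times, the longest HEYA8 run averaged 8.09 peaks and reached 15 at most (permutation p = 0.001, the smallest possible; labels were permuted as if neighbours were independent). The next HEYA8 runs were 15 peaks over 9.22 Mb of chromosome 2, starting at 207027009, and 11 peaks over 8.73 Mb of chromosome 3, starting at 160471981. The longest OVCAR8 run, 10 peaks over 1.29 Mb of chromosome 19 from 20727403, was within the permuted range (mean 7.74, at most 13, permutation p = 0.09).

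HEYA8-only peaks were more often clustered than OVCAR8-only peaks. Another HEYA8-only peak lay within 5 kb for 591 of 2949 (20.04%, 18.6 to 21.5), and another OVCAR8-only peak for 282 of 2786 (10.1%, 9.06 to 11.3). The share was higher in HEYA8 on 19 chromosomes and in OVCAR8 on 4 (exact sign test over chromosomes, two-sided p = 0.0026). Clusters of at least 4 line-only peaks, each within 5 kb of the next, numbered 9 in HEYA8 and 3 in OVCAR8. The largest HEYA8 cluster held 6 peaks on chromosome 8 from 101715279 to 101728027, and the largest OVCAR8 cluster held 6 on chromosome 15 from 39873251 to 39890513. Neither contained a peak of the other line. Some smaller HEYA8 clusters did, while others held none. The most was 3 OVCAR8 peaks, within a cluster of 5 on chromosome 7 from 99684830 to 99694199, among the largest clusters listed.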

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

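Alternatives that used file order, shifts by 50 to 500 kb, left-out chromosomes, regions, line-only peaks or clusters were added after the data had been seen. In all, 23 alternatives kept the direction and the side of the threshold or gave a similar count, and 8 counts moved further. No tested direction reversed, but the balance of uneven regions between the lines did. The 23 are not independent checks. With most peaks near 500 bp wide, midpoints within 500 bp is nearly the same rule as 1 bp of overlap. Line-only peaks per chromosome hold the same differences in count as all peaks. The 3481 shared peaks became 1429 when only peaks of at least the median width were kept, 1950 with the peaks up to the middle of each file and 1926 with the first 3133 peaks of each, settings that keep fewer peaks by construction. The share of HEYA8 peaks that was shared went opposite ways: from 54.1% it fell to 39.7% with the width limit and rose to 60.7% and 61.5% with file order. Reciprocal overlap of at least 50%, midpoints within 500 bp and extension by 1 kb gave 2737, 3491 and 4247. The fold over chance ranged from 47.4 to 298 and stayed past the threshold. The difference between chromosomes also held without chromosome 3, the chromosome whose omission weakened it most (chi-square 39.5, permutation p = 0.0083). It held among line-only peaks with whole 1 Mb blocks exchanged between the lines (permutation p = 0.0001, the smallest possible). Line-only log2 ratios of adjoining 5 Mb regions were correlated at 0.41, above the range of regions shuffled within chromosomes. Blocks of 1 Mb are shorter than that, so the block test still understates the error. The count of 12 uneven 5 Mb regions (3 with more HEYA8-only peaks and 9 with more OVCAR8-only) was the least stable. It was 16 with 10 Mb regions (9 and 7), 6 with 2 Mb regions, 4 with region boundaries moved midway, 4 with the peaks up to the middle of each file, 26 when line-only peaks within 5 kb of the other line were left out (12 and 14), and 1 when line-only peaks of a line within 5 kb were counted once. In that last setting 51 regions had an unadjusted p under 0.05, against 56, and all 12 kept their direction. Because the 12 had been picked for uneven counts, their kept direction says little. In 3 of the 11 lost regions the counts were the same, so clusters within them did not end the call. Their unadjusted p rose because the list totals had fallen unequally. On chromosome 15 at 35 to 40 Mb, counting neighbours once left 4 OVCAR8-only sites, below the 5 needed for testing, which ended that call. For the rest the cause was not tested. Alternatives that needed a transcription start site, a promoter sequence or a genome (distance to the start site, gene assignment, CpG-rich background, motif, motif window and motif control) were not run, nor were a second score column, the placement that keeps the distance to a start site, and the chromosome comparison on promoter peaks. Depth limits every statement about absent peaks: a line-only peak means only that the other list has none there, and with read counts unknown it cannot be said how far below the threshold the other library was.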

Other observations

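The tests of depth, of chromosome 6 (both) and of early HEYA8 peaks (both) were chosen after the patterns they bear on had been seen; the copy-number test was written before its value, but the requirement that it hold without each chromosome was added after that value had weakened without chromosome 3. The first pattern is the unevenness of line-only peaks between regions. If the lists had merely been ended at different depths, the balance of line-only peaks in a region would be unrelated to where its shared peaks stand in the files. Over 243 regions of 5 Mb with at least 5 shared peaks they were related: where HEYA8-only peaks prevailed, shared peaks also stood earlier in the HEYA8 file. File order, whose meaning is not stated, was taken as a rank. Spearman's rho was 0.48 (permutation p = 0.0001, the smallest possible) and Pearson's r was 0.47, and rho was 0.49 without chromosome 6. This argues against depth alone, within limits. Both measures come from the same files, so their relation is not independent evidence of unevenness. Regions were also shuffled as if independent, although adjoining ones were correlated, so this p understates the error. Copy number, which differs between cancer lines and acts over long stretches of DNA, may contribute. Log2 ratios of regions 15 to 25 Mb apart were correlated (mean r = 0.197, permutation p = 0.006), above the range of shuffled regions as that test had first required. Without chromosome 3 the mean was 0.100 (permutation p = 0.13), so the result at this distance rests on that chromosome. Adjoining regions were correlated at 0.41 (permutation p = 0.001). Regions were shuffled within chromosomes, which keeps each chromosome's mean, so a difference of a whole chromosome could not be detected. Copy number therefore stays open. Line-specific activity of whole regions would look alike, was not tested, and the input libraries that could measure copy number were not analysed here.

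The second pattern is the cluster of OVCAR8 peaks on chromosome 6 between 25 and 30 Mb. A gain of the whole chromosome in OVCAR8 is argued against by the rest of chromosome 6. The log2 ratio of line-only peaks there was -0.19 (95% interval -0.53 to 0.15), an average over stretches of opposite direction. In the region the ratio was -3.81 (-5.27 to -2.35), but the region had been chosen for its counts, which makes its own ratio extreme. Both ratios lack the 0.5 added to counts elsewhere for regions, with which the region's ratio was -3.65. That these peaks came from near the end of the OVCAR8 file is argued against too: a peak of the region listed only in OVCAR8 stood earlier than one elsewhere with a probability of 0.824 (permutation p = 5e-05, the smallest possible), at a median place of 1718 against 4418. What the order means is not stated, so whether these peaks were weak was not tested. A gain of this region alone, reads shared between near-identical sequences and a difference in ETS1 binding between the lines were not tested and remain open.

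The third pattern is that 128 peaks in the first of 10 equal parts of the HEYA8 file, including its first peak, had no overlapping OVCAR8 peak; the same part of the OVCAR8 file held 75 without a HEYA8 partner, 60% of them within 5 kb of a HEYA8 peak. A shift to an adjoining window of about 500 bp is argued against for most of them, since 22.7% (29 peaks, 95% Wilson interval 16.3 to 30.6) had an OVCAR8 midpoint within 1 kb, although local shifts gave 1.62% on average. A candidate explanation for more of them is another window of a broader enriched stretch: 64.8% (83) had an OVCAR8 peak within 5 kb, against 6.48% on average and 10.9% at the upper 95% bound when the OVCAR8 list was shifted locally. Of the 83, 54 lay 1 to 5 kb away, 6 had a nearest OVCAR8 peak that already overlapped another HEYA8 peak, and separate neighbouring sites would give the same distances and were not tested. The remaining 45 had no OVCAR8 peak within 5 kb, and a difference between the lines was not tested for them.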
